A study of Mus musculus with 8 samples.

How the data were processed

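The study measured gene expression by RNA sequencing in 8 libraries of mouse neutrophils sorted from tumours, 4 from ICAM1-high (CD54-positive in the titles) and 4 from ICAM1-low (CD54-negative) cells. Per the labels' protocols, total RNA was extracted with an RNeasy Micro kit and 150 pg were made into a library with a QIAseq FX Single Cell RNA kit, which amplifies very small amounts of RNA. The tools named in the submitters' processing notes are Trim Galore 0.6.6 for trimming and Salmon 1.9.0 for quantification, with the genome build GRCm39 (mm39). The annotation, the settings and the way transcripts were summed to genes are not given in the sources used here. The values the authors deposited are estimated counts per gene, which need not be whole numbers, in 1 table with gene identifiers, symbols, lengths and a column per library; per the labels, each sample's description names its column.

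The table had 25669 rows. There, 88 gene identifiers were repeated under several symbols with identical values, so each identifier was kept once (25572). Of these, 25343 were found in the reference table of gene names, and 6495, mitochondrial genes and genes listed under their identifier, were given its symbol. The reference annotation at hand is of another genome build, so it was used for names only and no coordinates are given. Estimated counts were rounded to whole numbers for the count models. Counts were not corrected for gene length or GC content.

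Genes were filtered with edgeR's filterByExpr by group (13575 kept), libraries were scaled by TMM, and ICAM1-high was compared with ICAM1-low using edgeR 4.0.16 in R 4.3.3 (estimateDisp, glmQLFit and glmQLFTest, all robust where offered), with group as the only term and Benjamini-Hochberg adjusted p under 0.05 as the threshold. The standard error of a log2 fold change is its size divided by the square root of the test's F value. CPM values are counts divided by the TMM-adjusted library size, on the usual CPM scale, given as mean ± SD over 4 libraries. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may in part be technical. Totals of 15940328 to 21825096 counts came from 150 pg of RNA, and the sources used here mention no molecular identifiers, so counts need not equal molecules sampled. Floors cover counting error only.

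Gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. There were 15 pathway lists and, as a separate family, 11 cell type and 2 RNA quality lists (ribosomal proteins, mitochondrially encoded genes). Icam1 is on none of them. The lists were tested with camera at its preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, with limma 3.58.1, and p-values were adjusted within each family. Symbols that differed between a list and the table were matched for 2 genes. Marker lists were also summed as CPM per library and compared by a two-sided exact permutation test over the 70 assignments of 4 against 4, whose smallest p is 0.0286. Lists of cartilage matrix genes and of basement membrane and matrix remodelling genes were added after their values were seen and are used in 1 figure and the closing part only.

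The genes named were Icam1, the 15 genes with the largest positive and the 15 with the largest negative log2 fold change among those past the threshold, with an average log2 CPM of 4 or more and the same direction in all 4 same-numbered pairs, leaving out predicted genes, pseudogenes and receptor segments, and the 4 tested members of each pathway list with the smallest p. Of the latter, the text prints those past the threshold and the foremost of lists with none. Other list members are named where a count needs them. Results of 2 genes are not reported here, and these genes, like the added lists, were left out of the search for libraries far from their group after it was first run; the genes remain in all counts of genes and list tests.

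The fitting steps were tested on simulated counts with the real library sizes and spread (13202 genes tested, 200 changed). Of 50 genes each changed 2-, 4-, 8- and 16-fold, 0, 1, 10 and 8 were recovered, and none of the 19 genes called was unchanged. The camera test called a simulated list of 25 genes that all went up, and it did not call an unchanged list. The simulated genes were drawn independently, so this could not show false calls that come from genes varying together. In the real data the estimated inter-gene correlation was 0.71 for the interferon-stimulated genes, far above the preset value.

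Alternatives were RLE and upper-quartile scaling, library sizes only, DESeq2 1.42.0, limma-voom with sample weights, no filter (at least 1 count), a filter of 10 CPM in at least 4 libraries, thinning to the smallest total, a test against a 1.5-fold change, a replicate term and leaving out each library. Those added after seeing the data were the fits without both libraries numbered 5 and without the ribosomal RNA genes Rn18s, mt-Rnr1 and mt-Rnr2. All 35 splits of the libraries into 4 and 4 were fitted in the same way. Figures were drawn with matplotlib 3.10.9.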

Results

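RNA was measured in neutrophils that had been sorted from PyMT-N tumours of C57BL/6 mice, given as C57/B6 in the series design, into a fraction with high and a fraction with low surface ICAM1. ICAM1, also called CD54, is an adhesion molecule that binds the beta-2 integrins of leukocytes. PyMT-N is the tumour line or tumour type that the series design names, and nothing else is said of it in the labels. There were 4 ICAM1-high and 4 ICAM1-low libraries, numbered 1, 2, 3 and 5 in both groups, each made from 150 pg of total RNA. Library totals ran from 15940328 estimated counts in ICAM1-low replicate 5 to 21825096 in ICAM1-high replicate 2. They did not differ between the groups past the threshold (exact permutation test over 70 assignments, p = 0.257, adjusted p = 0.643 over 5 library measures). Genes with at least 1 count numbered 16596 ± 887 in ICAM1-low and 18252 ± 1191 in ICAM1-high libraries (SD, n = 4; exact permutation p = 0.0857, adjusted p = 0.429). Ribosomal RNA took 4.54 ± 2.92% of the counts in ICAM1-low and 5.38 ± 3.77% in ICAM1-high libraries (SD, n = 4; exact permutation p = 0.714). Pearson's r of log2 CPM across genes was 0.77 to 0.85 among the ICAM1-high and 0.60 to 0.84 among the ICAM1-low libraries, and no pair of libraries differed by as little as counting noise. A count of 3, taken as the detection floor for counting error only, corresponded to 0.137 to 0.188 CPM.

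The comparison of ICAM1-high with ICAM1-low cells first depended on the gene on which the cells were sorted. Icam1 (ENSMUSG00000037405) was not past the threshold between the groups, with a log2 fold change of 0.67 ± 0.92 (SE, n = 4 against 4; edgeR adjusted p = 0.754). Its level was 48.2, 58.4, 42.4 and 122 CPM in ICAM1-high replicates 1, 2, 3 and 5, and 18.7, 9.25 and 4.31 CPM in ICAM1-low replicates 1, 2 and 3. The library labelled ICAM1-low replicate 5 held 138 CPM, above every ICAM1-high library. Icam1 was thus higher in ICAM1-high in 3 of 4 same-numbered pairs. The direction in the libraries numbered 5 turned with the scaling: with library sizes only it was 98.6 CPM in the library labelled ICAM1-low replicate 5 and 128 CPM in ICAM1-high replicate 5. Without the library labelled ICAM1-low replicate 5 the log2 fold change of Icam1 was 2.64 and past the threshold (edgeR adjusted p = 0.0483). It was 2.22 without both libraries numbered 5 (edgeR adjusted p = 0.0958) and 2.21 with limma-voom (adjusted p = 0.0563), neither past the threshold. The sort was on surface protein, so the mRNA is an indirect check of the labels.

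**Figure D1:**
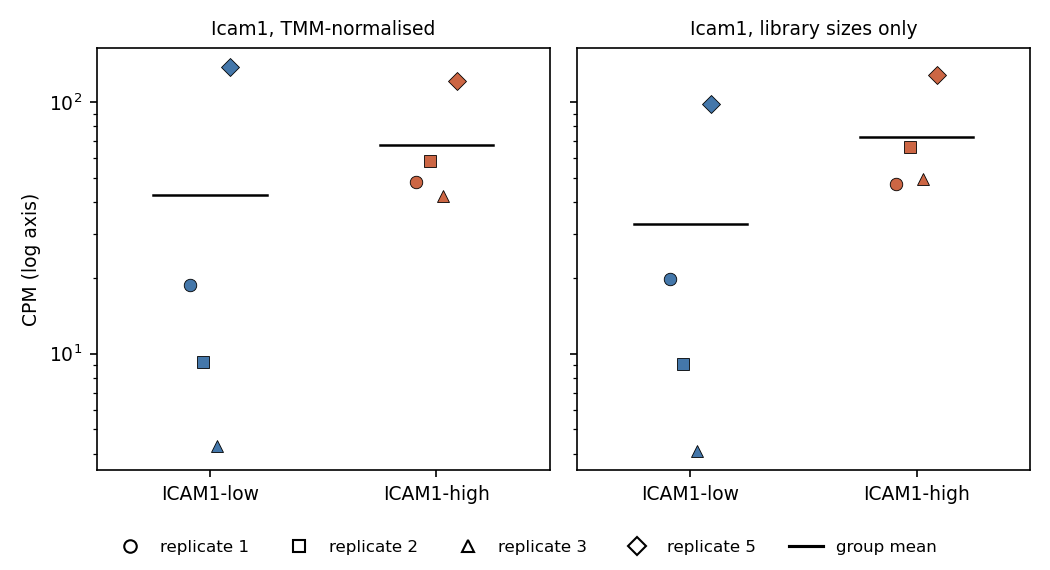
Icam1 in each library as CPM on a log axis, after TMM normalisation (left) and with library sizes only (right); symbols mark the replicate number and bars the group mean. ICAM1-low replicate 5 lies at 138 CPM on the left, above the 42.4 to 122 CPM of the ICAM1-high libraries, while ICAM1-low replicates 1 to 3 lie between 4.31 and 18.7 CPM.

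Sorted by surface ICAM1, the 2 fractions differed in genes of macrophages and antigen-presenting cells, which were higher in ICAM1-high libraries, and in neutrophil granule and surface genes, which were lower. Among 13575 genes tested, 166 were higher and 37 were lower in ICAM1-high libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). All 166 were higher and all 37 were lower in each of the 4 same-numbered pairs. These genes were called from the same libraries, so this adds no separate support. The median change was 14.2-fold among the higher and 9.35-fold among the lower genes. The biological coefficient of variation was 0.858, and in simulated data of this comparison 1 of 50 genes changed 4-fold and 10 of 50 changed 8-fold were recovered. Of the higher genes, 21 were on the fixed lists of macrophage, monocyte, dendritic cell, T and NK cell or B cell markers, and of the lower genes 11 were on the fixed neutrophil lists. At an unadjusted p under 0.05 the numbers were 1081 higher and 1216 lower. Upper-quartile scaling moved the median log2 fold change of all genes by 0.13 and library sizes alone by 0.24 from its value of -0.07 with TMM; the changes below are relative to the TMM scale. The counts changed when a library was left out, which also leaves fewer libraries to test. No called gene changed sign in these fits, which share most libraries with the main fit and so are no separate test. The counts were 4 higher and 0 lower without ICAM1-low replicate 1 and 42 and 1 without ICAM1-high replicate 1. They were 73 and 3 without ICAM1-low replicate 2 and 56 and 2 without ICAM1-high replicate 2. They were 121 and 48 without ICAM1-low replicate 3, 71 and 9 without ICAM1-high replicate 3 and 56 and 2 without ICAM1-high replicate 5. They were 337 and 241 without ICAM1-low replicate 5, and 219 and 190 without both libraries numbered 5, an alternative chosen after seeing the data.

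Among genes of at least moderate expression, the 15 largest increases were between 4.44 and 6.94 on the log2 scale. Mgl2 (ENSMUSG00000040950), a C-type lectin of macrophages and dendritic cells, went from 1.58 ± 0.858 CPM in ICAM1-low to 176 ± 109 CPM in ICAM1-high libraries (SD, n = 4), a log2 fold change of 6.79 ± 0.69 (SE; edgeR adjusted p = 0.00449). Il2ra (ENSMUSG00000026770), the alpha chain of the interleukin-2 receptor, went from 0.3 ± 0.165 to 37.5 ± 17.9 CPM, a log2 fold change of 6.94 ± 0.81 (edgeR adjusted p = 0.00749). The expressed-sequence locus AU020206 rose from 8.84 ± 3.29 to 368 ± 115 CPM (log2 fold change 5.38 ± 0.51; edgeR adjusted p = 0.0041), the smallest p of all genes. Ctla4, an inhibitory receptor of T cells, and Cd4, the co-receptor of helper T cells, rose by 6.67 ± 1.37 and 5.33 ± 1.13 on the log2 scale. Il21r, the interleukin-21 receptor, rose by 6.67 ± 1.25, the B cell and macrophage receptor Cd180 by 4.77 ± 0.77 and the immune receptor Slamf7 by 4.97 ± 0.95. The others were the calcium channel gene Cacna1d (6.51 ± 1.12), Zmynd15 (6.40 ± 1.08), Asb2 (5.48 ± 0.85), the receptor phosphatase gene Ptpro (5.37 ± 1.0), the TGF-beta family gene Gdf3 (5.05 ± 1.06), the receptor kinase gene Grk3 (4.73 ± 0.71) and Rnf180 (4.44 ± 0.91), with edgeR adjusted p from 0.0041 to 0.0451 over these 15 genes. Ctla4 stood at 0 CPM in ICAM1-low replicates 2 and 3, and Il21r and Cacna1d at 0 CPM in ICAM1-low replicate 3. Cd4, Slamf7, Zmynd15, Gdf3 and Rnf180 were each under the detection floor in an ICAM1-low library. The size and rank of these fold changes are therefore uncertain.

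The largest decreases included genes that mark neutrophils or fill their granules. Ngp (ENSMUSG00000032484), a neutrophil granule protein gene, fell from 609 ± 327 to 38.4 ± 25.7 CPM (SD, n = 4), a log2 fold change of -3.99 ± 0.71 (SE; edgeR adjusted p = 0.0239). Ltf, which encodes lactoferrin, fell from 1941 ± 1009 to 148 ± 125 CPM (log2 fold change -3.71 ± 0.77; edgeR adjusted p = 0.043). Ly6g (ENSMUSG00000022582), which encodes a surface protein used to identify mouse neutrophils, fell from 36.4 ± 7.09 to 1.93 ± 1.60 CPM (log2 fold change -4.23 ± 0.92; edgeR adjusted p = 0.0486). Retnlg (ENSMUSG00000022651) fell by 3.28 ± 0.48 on the log2 scale, with the smallest p among the lower genes (edgeR adjusted p = 0.0119). The neutrophil surface gene Cd177 changed by -3.43 ± 0.65, Padi4, which encodes the histone-citrullinating enzyme of neutrophils, by -3.64 ± 0.77 and Lrg1 by -4.23 ± 0.85. Phospho1 had the largest decrease, -6.24 ± 1.28. The others were Zfand4 (-4.83 ± 0.91), Zfp9 (-4.46 ± 0.94), Ankrd33b (-3.79 ± 0.76), Mrgpra2a (-3.51 ± 0.69), Mrgpra2b (-3.42 ± 0.57), the p38 kinase gene Mapk13 (-3.30 ± 0.56) and the cytokine gene Il36g (-3.30 ± 0.66). Mrgpra2a and Mrgpra2b are close paralogs, so the split of reads between them is uncertain. Of these 30 named genes, 4 stayed past the threshold without ICAM1-low replicate 1, 5 without ICAM1-high replicate 1, 6 without ICAM1-high replicate 5, 9 without ICAM1-high replicate 2, 9 without ICAM1-high replicate 3, 10 without ICAM1-low replicate 2, 26 without ICAM1-low replicate 3 and 30 without ICAM1-low replicate 5. None of the 30 changed direction in these fits, and the highest edgeR adjusted p among them was 0.15. The 30 were picked for the same direction in all 4 pairs, so their kept direction is no separate support. The log2 fold changes that moved by over 1 were those of Ptpro (7.17), Lrg1 (-2.98) and Ankrd33b (-2.62) without ICAM1-low replicate 5, Cd4 (7.64) and Zfand4 (-3.55) without ICAM1-low replicate 2, Ctla4 (8.66) and Cacna1d (7.58) without ICAM1-low replicate 1, and Il21r (5.42) and Zmynd15 (5.37) without ICAM1-high replicate 5.

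**Figure D2:**
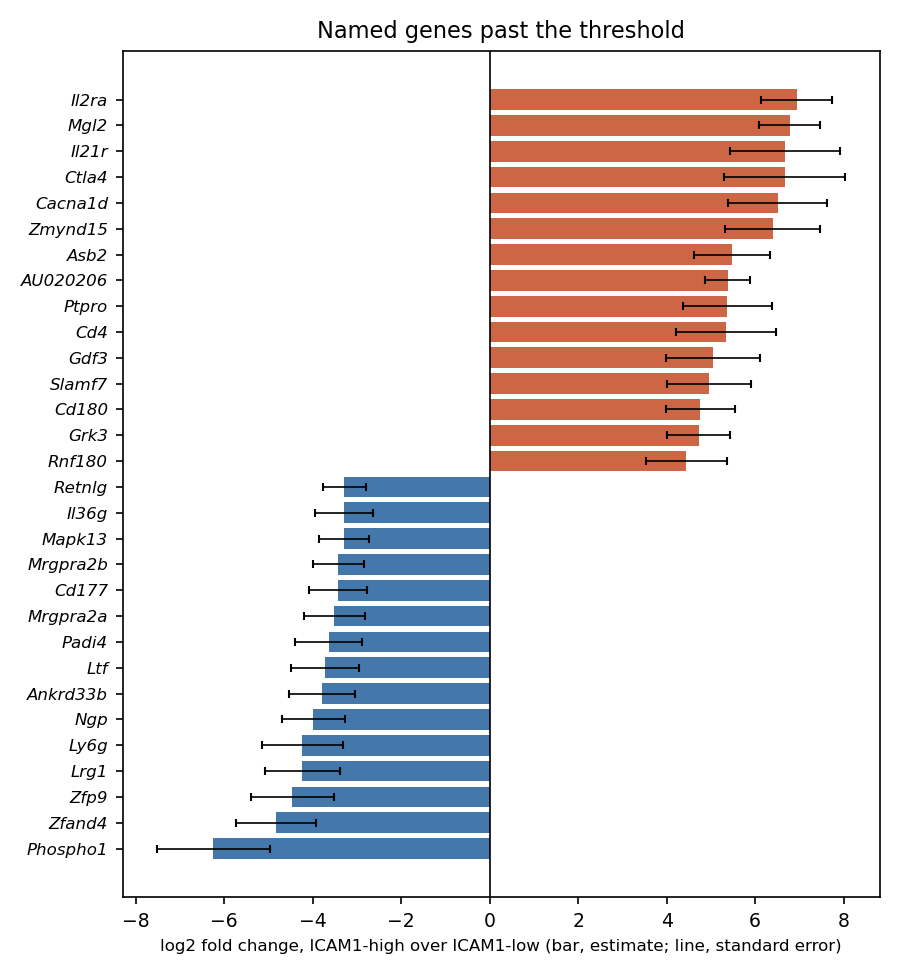
Log2 fold change of ICAM1-high over ICAM1-low for the 30 named genes past the threshold, with standard errors (4 libraries per group). Il2ra (6.94) and Mgl2 (6.79) lead the higher and Phospho1 (-6.24) the lower genes.

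Genes of circulating mature neutrophils and neutrophil identity markers were lower in ICAM1-high libraries, while the immature neutrophil list was split. Of 30 genes typical of circulating mature neutrophils, 5 fell and none rose (24 fell when adjusted over the list alone): Retnlg, S100a8, Lrg1, Padi4 and Ly6g. All 30 had negative log2 fold changes, with a median of -2.73. S100a8, a calcium-binding alarmin gene, fell from 1864 ± 920 to 199 ± 115 CPM (SD, n = 4; log2 fold change -3.23 ± 0.64 SE; edgeR adjusted p = 0.0369). The list was lower by camera with its preset correlation (adjusted p = 1.17e-21; adjusted p = 0.364 with an estimated correlation). Without ICAM1-low replicate 5 the medians of the circulating mature neutrophil genes and the neutrophil identity markers below were -1.69 and -1.61. Among 22 tested genes of immature neutrophil granules and precursors, 6 fell, namely Ngp, Cd177, Serpinb1a, Ltf, Ly6c2 and Adpgk, and 1 rose, the dipeptidyl peptidase gene Ctsc (7 and 11 higher and lower when adjusted over the list alone, in that order). Ctsc went from 400 ± 91.3 to 3085 ± 1034 CPM (log2 fold change 2.95 ± 0.48; edgeR adjusted p = 0.0167). In all 4 pairs 8 members of the list were higher and 12 lower. Its summed CPM was 7450 in ICAM1-low and 11382 in ICAM1-high libraries and was higher in ICAM1-high in all 4 pairs. By camera the list was lower, with a median of -1.73 (camera adjusted p = 0.0368, and 0.419 with an estimated correlation). That call was lost without ICAM1-high replicate 3 (camera adjusted p = 0.134), without ICAM1-low replicate 5 (0.167), with limma-voom (0.142) and with the stricter filter (0.0611). The neutrophil identity markers, 15 genes of which 3 fell (12 when adjusted over the list alone), had a median of -2.68 (camera adjusted p = 5.51e-13; adjusted p = 0.107 with an estimated correlation). Their summed CPM was 25007 ± 21958 in ICAM1-low and 5581 ± 1424 in ICAM1-high libraries (SD, n = 4; exact permutation p = 0.0286, the smallest that 4 against 4 can give, adjusted p = 0.0743). Of the 15 identity markers, 11 are also on another list.

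Macrophage genes formed the opposite group. Of 17 macrophage markers, 12 rose and none fell (15 rose when adjusted over the list alone), and 16 were higher in all 4 same-numbered pairs. The median log2 fold change was 3.28 (camera adjusted p = 2.84e-24; adjusted p = 0.00321 with an estimated correlation). The complement genes C1qc and C1qb rose from 153 to 2470 CPM and from 37.2 to 719 CPM, Apoe, the apolipoprotein E gene, from 132 to 2050 CPM, and the mannose receptor gene Mrc1 from 46.6 to 594 CPM, with log2 fold changes of 4.02 ± 0.59, 4.27 ± 0.56, 3.96 ± 0.65 and 3.67 ± 0.43 (SE, n = 4 against 4; edgeR adjusted p from 0.00749 to 0.017). Summed over the list, ICAM1-high libraries held 10950 ± 4771 CPM and ICAM1-low libraries 1385 ± 235 CPM (SD, n = 4), a 7.91-fold difference (exact permutation p = 0.0286, adjusted p = 0.0743). Of these markers 16 were above 1 CPM in every ICAM1-low library. The 9 monocyte markers did not move together: Ccr2, Cx3cr1 and Ms4a4c rose and Ly6c2 fell (3 higher and 3 lower when adjusted over the list alone), and the list was not past the camera threshold (adjusted p = 0.423, direction up against a median of -0.52) but was past it by fry (adjusted p = 0.0486, direction up). Their summed CPM, of which Fn1 was the largest part, was 12396 ± 3755 in ICAM1-low and 3807 ± 1004 in ICAM1-high libraries (SD, n = 4; exact permutation p = 0.0286, adjusted p = 0.0743) and lower in all 4 pairs.

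Markers of other leukocytes were also higher in ICAM1-high libraries. Of 11 tested dendritic cell markers 5 rose, H2-Eb1, H2-Aa, H2-Ab1, Cd74 and Ciita (7 when adjusted over the list alone; median 3.65; camera adjusted p = 1.26e-10, adjusted p = 0.00321 with an estimated correlation). These 5 are genes of MHC class II presentation and belong to the antigen presentation list too; the dendritic cell receptor gene Xcr1 stood at 5.40 CPM in ICAM1-high and 0.243 CPM in ICAM1-low libraries and was not past the threshold (edgeR adjusted p = 0.228). Of 14 T and NK cell markers only Cd4 rose (3 when adjusted over the list alone), although all 14 had positive log2 fold changes (median 2.89; camera adjusted p = 4.06e-09, adjusted p = 0.107 with an estimated correlation). Their summed CPM was 276 ± 156 in ICAM1-high and 41.9 ± 40.8 in ICAM1-low libraries (SD, n = 4; exact permutation p = 0.0286, adjusted p = 0.0743). Without ICAM1-low replicate 2 the medians of the T and NK cell markers and of the B cell and plasma cell markers were 4.66 and 4.47. B cell and plasma cell markers summed to 978 ± 885 CPM in ICAM1-high and 181 ± 186 CPM in ICAM1-low libraries (SD, n = 4). These sums were higher in ICAM1-high in all 4 pairs, but their exact permutation p was 0.0571 (adjusted p = 0.0825). The groups overlapped, with 452 CPM in ICAM1-low replicate 2 and 308 CPM in ICAM1-high replicate 3. None of 10 B cell and plasma cell markers passed the gene-level edgeR test, over all genes or adjusted over the list alone, and all 10 had positive values (median 2.46; camera adjusted p = 5.2e-05, adjusted p = 0.279 with an estimated correlation). Fibroblast markers went the other way, with 1 of 12 lower, the collagen gene Col6a1 (3 when adjusted over the list alone; median -1.26; camera adjusted p = 6.33e-05, adjusted p = 0.139 with an estimated correlation). The epithelial and mammary tumour (8 tested, median -1.75, and -0.51 without ICAM1-low replicate 5), endothelial (5 tested, -1.36), mast cell, basophil and eosinophil (4 tested, -0.88, 1 lower when adjusted over the list alone) and erythroid and platelet (4 tested, 0.64) markers were not past the threshold as lists (camera adjusted p from 0.423 to 0.853). In the last of these lists Pf4, which is also a macrophage marker here, rose (1 when adjusted over the list alone). Cytosolic ribosomal protein genes had a median of 1.01 with 79 of 80 positive and no gene past the edgeR threshold (camera adjusted p = 3.12e-11, adjusted p = 0.279 with an estimated correlation), and the mitochondrially encoded genes a median of 0.05 (camera adjusted p = 0.543).

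**Figure D3:**
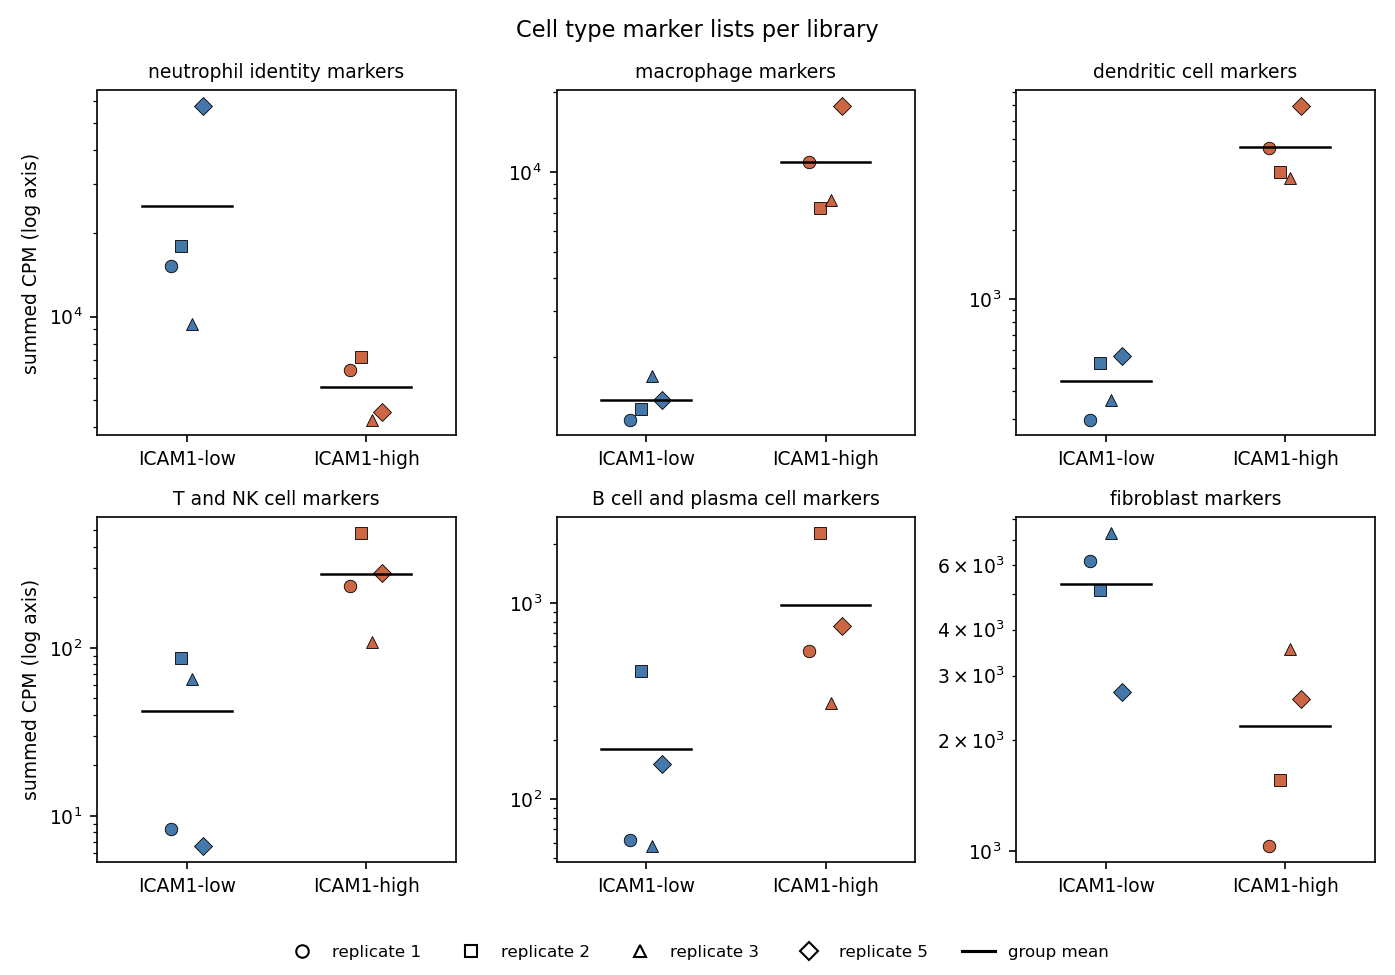
Summed TMM-normalised CPM of 6 marker lists in each library, on log axes; symbols mark the replicate number and bars the group mean. Macrophage markers sum to 7333 to 17697 CPM in ICAM1-high and to 1165 to 1710 CPM in ICAM1-low libraries, and neutrophil identity markers reach 57505 CPM in ICAM1-low replicate 5.

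Some antigen presentation, lysosomal and chemotaxis genes rose, as did macrophage markers. Of 24 antigen presentation genes 7 rose and none fell (11 rose when adjusted over the list alone), all of them in the MHC class II pathway: H2-Eb1, H2-Aa, H2-DMa, H2-Ab1, Cd74, H2-DMb1 and the class II transactivator gene Ciita. H2-Eb1 went from 63.3 ± 16.2 to 904 ± 376 CPM (SD, n = 4), a log2 fold change of 3.84 ± 0.50 (SE; edgeR adjusted p = 0.00992), and H2-Aa from 101 ± 36.2 to 1115 ± 375 CPM (3.47 ± 0.50). The list median was 1.10 (camera adjusted p = 2.51e-12; adjusted p = 0.364 with an estimated correlation), and 1.92 without ICAM1-low replicate 5. Of 30 lysosome and lipid handling genes 3 rose, among them the cathepsin gene Ctss and Cd68, and none fell (10 higher and 2 lower when adjusted over the list alone), with 20 positive and 10 negative log2 fold changes; Ctss went from 309 ± 182 to 3088 ± 1969 CPM (log2 fold change 3.32 ± 0.64; edgeR adjusted p = 0.0347). The list median was 0.78 (camera adjusted p = 1.79e-04; adjusted p = 0.364 with an estimated correlation). Of 24 chemotaxis receptors and ligands 7 rose and none fell (12 higher and 4 lower when adjusted over the list alone), with 13 positive and 11 negative log2 fold changes. Among them were the chemokine receptors Ccr2 and Cx3cr1, the complement receptor C3ar1 and the ligands Ccl2, Ccl7 and Cxcl16. Ccr2 rose by 3.81 ± 0.50, C3ar1 by 3.41 ± 0.51 and Cx3cr1 by 3.06 ± 0.54 on the log2 scale (SE; edgeR adjusted p from 0.00992 to 0.0239). The list median was 1.81 (camera adjusted p = 5.98e-05; adjusted p = 0.364 with an estimated correlation), 0.03 with the stricter filter, which kept its call, and 2.54 without ICAM1-low replicate 5. By fry, the circulating mature neutrophil, antigen presentation and lysosome lists were the 3 of 15 lists past the threshold (adjusted p = 0.0488 each).

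Lists of metabolic and stress genes had lower medians in ICAM1-high libraries without single genes past the threshold. Of 30 hypoxia and glycolysis genes 28 had negative log2 fold changes and 15 were lower in all 4 pairs, with a median of -0.61, and none passed the edgeR test over all genes (3 lower when adjusted over the list alone). The glucose transporter gene Slc2a3 stood at 1713 ± 1785 CPM in ICAM1-low and 171 ± 128 CPM in ICAM1-high libraries (SD, n = 4; edgeR adjusted p = 0.0763), with 4337 CPM in ICAM1-low replicate 5 and 421 to 1289 CPM in ICAM1-low replicates 1 to 3. The list was past the threshold by camera (adjusted p = 1.79e-04; adjusted p = 0.419 with an estimated correlation), and without ICAM1-low replicate 5 its median was -0.31 (camera adjusted p = 0.011). The immediate-early and dissociation stress genes, led by Egr1 (1926 ± 1159 against 436 ± 149 CPM; edgeR adjusted p = 0.0874), had a median of -1.01 (2 of 25 lower when adjusted over the list alone; camera adjusted p = 0.0149; adjusted p = 0.518 with an estimated correlation). Their call was lost without ICAM1-high replicate 3 (camera adjusted p = 0.0709), with limma-voom (0.132) and without ICAM1-low replicate 5 (0.313), where the median was -0.25. The unfolded protein and integrated stress response genes, led by the asparagine synthetase gene Asns (35.3 ± 14.2 against 8.36 ± 1.72 CPM; edgeR adjusted p = 0.0868), had a median of -0.83 (none of 25 when adjusted over the list alone; camera adjusted p = 0.0328; adjusted p = 0.364 with an estimated correlation). That call was lost without ICAM1-high replicate 2 (camera adjusted p = 0.0955), ICAM1-high replicate 3 (0.0949) or ICAM1-low replicate 5 (0.0827, with a median of -0.38) and with the stricter filter (0.103). Of the 15 pathway lists 8 were past the camera threshold with the preset correlation and none with an estimated one; at an unadjusted p the latter had 1 list, the circulating mature neutrophil genes, under 0.05 (p = 0.0305). A count of 8 lists or more was also reached by 19 other splits of the 8 libraries into 4 and 4.

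The remaining 7 lists were not past the camera threshold and each held 1 gene or none that rose. Of 30 NF-kB target and inflammatory genes Cd83, an activation marker of antigen-presenting cells, rose from 46.1 ± 25 to 485 ± 184.96 CPM (SD, n = 4; log2 fold change 3.39 ± 0.54 SE; edgeR adjusted p = 0.0153), while the list median was -0.56 (camera adjusted p = 0.531). Of 35 interferon-stimulated genes none passed the edgeR test over all genes (1 higher and 1 lower when adjusted over the list alone). Mx1 stood at 210 ± 37.4 CPM in ICAM1-high and 18.7 ± 18.3 CPM in ICAM1-low libraries (edgeR adjusted p = 0.0729), and Slfn4 at 380 ± 60.2 and 4791 ± 7000 CPM (edgeR adjusted p = 0.0803), with 15267 CPM in ICAM1-low replicate 5 and 812 to 1941 CPM in ICAM1-low replicates 1 to 3. The interferon list had a median of -0.09 with the camera direction up (adjusted p = 0.199). The median was 0.05 with upper-quartile scaling and 0.29 with library sizes only. With the list past the threshold it was 0.99 with limma-voom (camera adjusted p = 2.02e-04) and 1.54 without ICAM1-low replicate 5 (camera adjusted p = 2.99e-07). Both calls used the preset correlation of 0.01, far below the 0.71 estimated for this list in the main fit. An estimated correlation was not tried for these 2 fits. Without ICAM1-low replicate 5, 5 of the 35 genes were higher and 1 lower past the edgeR threshold. Without both libraries numbered 5 there were 0 and 0. In ICAM1-low replicate 5 the interferon list summed to 27775 CPM, against 1758 to 3324 CPM in ICAM1-low replicates 1 to 3, and the NF-kB list to 51997 against 5923 to 9224 CPM. Among the adhesion molecules, integrins and ligands (median -0.55; camera adjusted p = 0.199) Vcam1, a ligand of the integrin VLA-4, rose from 41.4 ± 16.3 to 366 ± 102 CPM (log2 fold change 3.14 ± 0.47; edgeR adjusted p = 0.0127), and the tetraspanin gene Cd9 fell from 316 ± 141 to 75.5 ± 17.1 CPM (-2.06 ± 0.45; edgeR adjusted p = 0.0486), with 1 higher and 5 lower when adjusted over the list alone. The fibronectin gene Fn1, at 11297 ± 3428 against 2350 ± 819 CPM, was not past the threshold (edgeR adjusted p = 0.0571). In the immunosuppression list (median -0.46; camera adjusted p = 0.738) Trem2, a lipid receptor of macrophages, rose by 3.45 ± 0.60 on the log2 scale. In the oxidative burst list (median 0.21; camera adjusted p = 0.34) the proton channel gene Hvcn1 rose by 3.28 ± 0.45. The tumour-associated neutrophil list had a median of -0.36 (camera adjusted p = 0.844). In the survival and apoptosis list (median -0.37 with a mean of 0.16; camera adjusted p = 0.836, direction up) the BCL2 family gene Bcl2a1a rose by 3.64 ± 0.80. Bcl2a1a has close paralogs in Bcl2a1b and Bcl2a1d, so its share of their reads is uncertain. Adjusted over the list alone, the last 4 lists held 2, 1, 1 and 4 higher and 4, 0, 0 and 1 lower genes, and the NF-kB list 1 higher gene. Without single libraries 3 others of these lists passed the camera threshold with the preset correlation: the NF-kB list without ICAM1-low replicate 3 (adjusted p = 0.0304), the adhesion list without ICAM1-low replicate 1 (0.0485) and the oxidative burst list without ICAM1-low replicate 5 (0.0292).

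**Figure D4:**
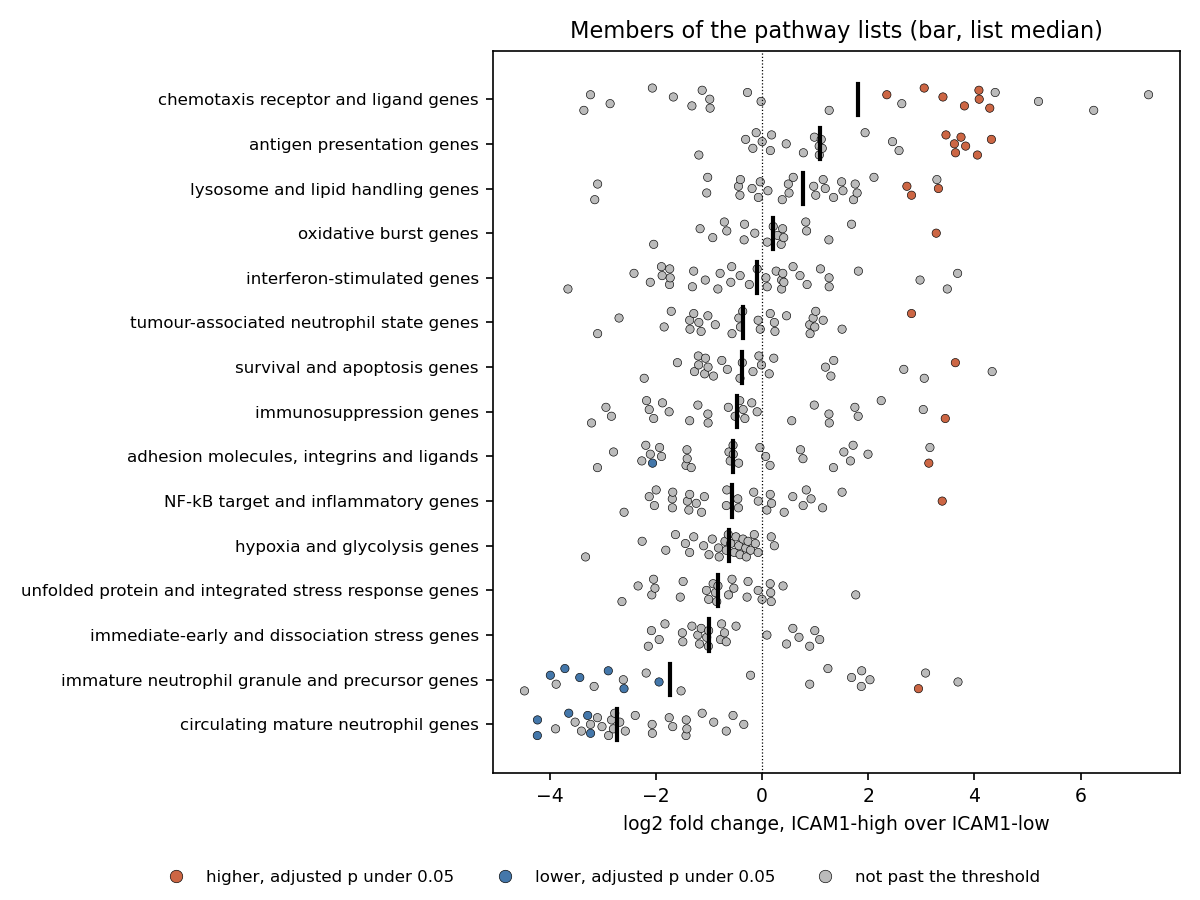
Log2 fold changes of the tested members of the 15 pathway lists, ordered by list median (black bar); orange members were higher and blue members lower past the threshold, grey ones were not. Medians run from -2.73 for the circulating mature neutrophil genes to 1.81 for the chemotaxis receptors and ligands.

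**Figure D5:**
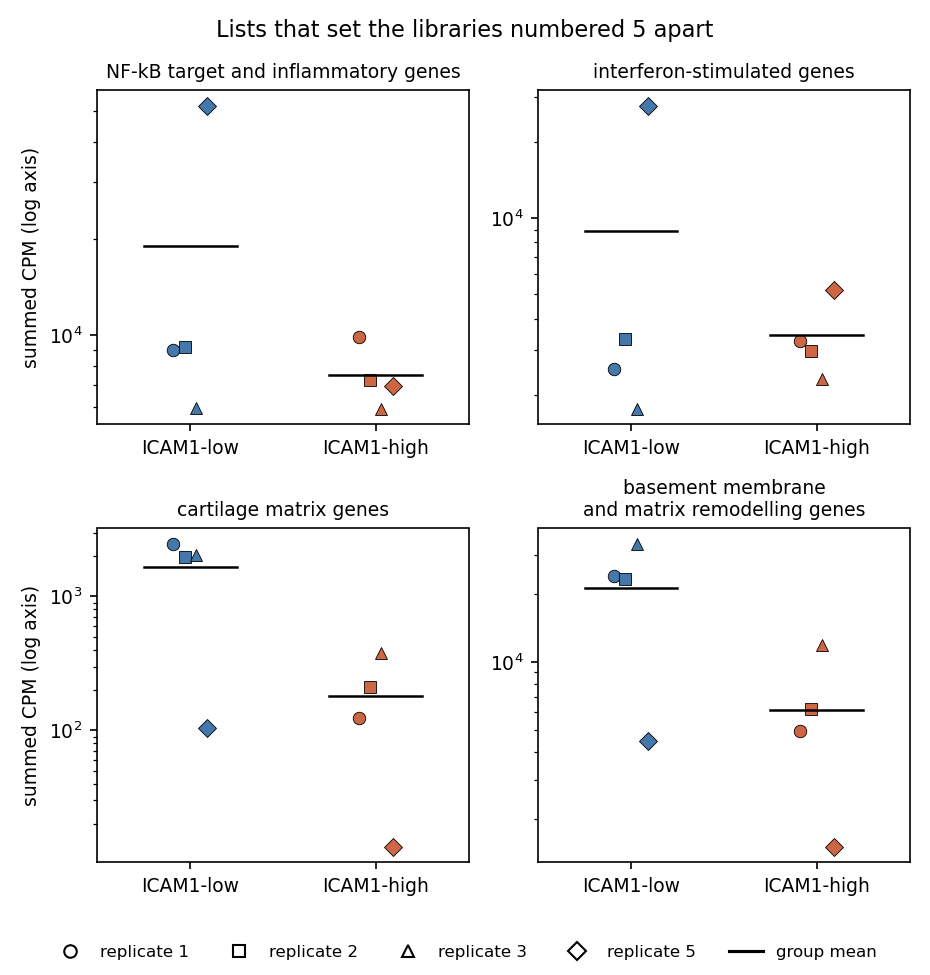
Summed CPM of 4 lists in each library on log axes, the lower 2 lists chosen after their values were seen; symbols mark the replicate number and bars the group mean. ICAM1-low replicate 5 has 51997 CPM of NF-kB genes and 105 CPM of cartilage matrix genes, against 5923 to 9224 and 1978 to 2479 CPM in ICAM1-low replicates 1 to 3.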

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

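Of 234 groups of 4 libraries examined (named genes, summed fixed lists and library measures in each group), 13 had 1 library far from the other 3 by Dixon's test on log2(CPM + 1) (library measures as they are), where chance gives about 1 in 20. On the CPM scale, tried after the results were seen, there were 34, of which 23 were ICAM1-low replicate 5. All explanations weighed in this part, and the counts over splits, were tested only after the results were seen. ICAM1-low replicate 5 accounted for 5 of the 13. It had 791 CPM of Nfil3 against 113 to 152 CPM in the other ICAM1-low libraries and 1214 CPM of Trem1 against 103 to 154 CPM. Its summed CPM was 15104 for lysosome and lipid handling genes (10738 to 11191 in the others), 9966 for survival and apoptosis genes (2384 to 2686) and 6818 for monocyte markers (13693 to 14957). The TMM factor of this library was 0.718, against 0.956 to 1.06 in the other ICAM1-low libraries. That scaling raises its CPM over library sizes only (138 against 98.6 CPM for Icam1), so its lysosome sum may stand apart through scaling alone. The search was not run with library sizes only. Among the other ICAM1-low libraries, replicate 1 had 25.9 CPM of Ly6g (38.8 to 41.1 in the others), replicate 2 had 3.62 CPM of Cd4 (0.0877 to 0.266), and replicate 3 had 34.2 CPM of Tnfrsf10b (4.05 to 5.40) and 515 CPM of S100a8 (2039 to 2461). ICAM1-high replicate 1 had 106 CPM of Pfkl (75.4 to 76.4) and 10.9 CPM of Asns (7.24 to 7.68). ICAM1-high replicate 5 had 622 CPM of H2-Ab1 (202 to 235), and ICAM1-high replicate 3 had 12105 summed CPM of cytosolic ribosomal protein genes (22073 to 23284).

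Macrophage genes were higher and neutrophil genes lower in ICAM1-high libraries. A lower share of neutrophil RNA alone would raise other cell types alike, and is argued against by the medians of macrophage and fibroblast markers, which lay 4.54 apart on the log2 scale, beyond the interquartile range of either list (1.57 and 1.40). RNA of macrophages or related myeloid cells in the ICAM1-high libraries is a candidate explanation. The labels name a sort but not the gate that would exclude such cells. In all 4 pairs 16 of 17 macrophage markers were higher, with C1qc at 2470 and Apoe at 2050 CPM. That restates the pattern, so it does not favour this source over another. Neutrophils that themselves carry macrophage and antigen presentation transcripts cannot be told apart from RNA of such cells in bulk libraries. T, NK, B and plasma cell markers also had a median of 2.85, which points to RNA of other cells but not to how much of the macrophage signal they bring. The ICAM1-low side held matrix genes as well. Basement membrane and matrix remodelling genes, a list chosen after its values were seen, averaged 26963 summed CPM in ICAM1-low replicates 1 to 3. Neutrophil identity markers averaged 14175 CPM there. In ICAM1-low replicate 5 these sums were 4438 and 57505 CPM. How far the cells behind the matrix genes shape the genes lower in ICAM1-high was not tested. A biological difference between ICAM1-high and ICAM1-low neutrophils stays open and was not tested further.

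ICAM1-low replicate 5 stood above ICAM1-low replicates 1 to 3 in Icam1 and in the summed interferon and NF-kB genes. Neither Icam1 nor these sums were among the 13 groups flagged by Dixon's test above. The pattern was noticed in the values. A swap of the 2 libraries numbered 5 is argued against by the macrophage markers, which summed to 1384 CPM in ICAM1-low replicate 5 and to 17697 CPM in ICAM1-high replicate 5, each on its own group's side. Whether a larger share of neutrophil RNA in that library alone explains the interferon-stimulated genes was not settled. Their median log2 difference from replicates 1 to 3 (3.35) exceeded that of the circulating mature neutrophil genes (1.08) by 2.27, beyond the interquartile range of either list. It exceeded that of the neutrophil identity markers by 1.46, below the interquartile ranges of the interferon and identity lists (1.66 and 2.07). The comparison with the mature neutrophil list argues against this explanation, and that with the identity list does not. For the NF-kB target genes the same explanation cannot be told apart from a difference in cell state, since their excess over these lists was 1.23, between the interquartile ranges of the NF-kB (1.04) and mature neutrophil genes (1.48), and 0.42, below both. No biological explanation was tested, since the labels give no variable that sets this library apart.

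The summed CPM of the cartilage genes was lower in each library numbered 5 than in replicates 1 to 3 of the same group, though not that of every member (Sox9 stood at 53.6 CPM in ICAM1-low replicate 5 and at 6.07 to 19.3 CPM in replicates 1 to 3). Whether RNA from epithelial mammary tumour cells was the source cannot be told. Epcam, Krt8 and Krt18 were low in ICAM1-low replicates 1 to 3, at 0.22% of the summed CPM of the cartilage list (4.76 against 2164 CPM). The cartilage genes were chosen after their values were seen, so this share cannot decide the question. The whole epithelial and mammary tumour list, mostly Trps1, had a mean sum of 444 CPM in ICAM1-low replicates 1 to 3 and 295 CPM in replicate 5. Its milk protein gene Csn3 went with the cartilage genes (22.8 to 138 CPM against 0). Fibroblasts as the one source cannot be told apart: from replicates 1 to 3 to replicate 5 of ICAM1-low, the median log2 differences of the cartilage genes and the fibroblast markers were -5.67 and -1.01, which differ by -4.66, but the cartilage genes were chosen after their values were seen. Another matrix-producing cell, or a tumour cell of mesenchymal type, stays open and was not tested, and no biological explanation could be drawn from the groups.

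The 203 genes past the threshold were not matched by any other of the 35 splits of the 8 libraries into 4 and 4 (1 split, the real one, the fewest possible), where the highest other count was 1. This argues against chance as the source of that count, although other splits mix the groups and so have a larger spread. The 8 pathway lists past the camera threshold were reached or exceeded in 20 of the 35 splits (highest other, 13), and the 7 cell type and quality lists in 12 of 35 (highest other, 9), so chance is not excluded for the number of lists called with the preset correlation.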

How the results depend on the processing

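Tests without both libraries numbered 5 and without ribosomal RNA genes were chosen after seeing the data; the others were planned. The 166 genes higher in ICAM1-high became 125 with RLE, 212 with upper-quartile scaling, 245 with no filter, 184 with the stricter filter, 163 after thinning and 177 without ribosomal RNA genes, all within 1.5 times. The count moved further, and the cause was not tested, to 258 with library sizes only, 847 with the DESeq2 Wald test and 480 with limma-voom; it was 104 against a 1.5-fold change, a narrower question. The 37 genes lower in ICAM1-high became 745 with DESeq2, 376 with limma-voom, 120 with no filter, 61 with the stricter filter, 10 against a 1.5-fold change and 190 without both libraries numbered 5. Leaving out 1 library gave 4 to 337 higher and 0 to 241 lower genes. Of the main calls, DESeq2 kept 165 of 166 and 37 of 37 and limma-voom the same numbers, and no called gene changed sign under any alternative. All alternatives use the libraries from which the genes were called, so kept calls and signs are no separate support. Of the 30 named genes 27 stayed past the threshold with RLE, 28 with library sizes only, 29 with no filter, 18 against a 1.5-fold change and 23 without both libraries numbered 5. The stricter filter left 2 of the 30 without a value, and DESeq2 and the test against a 1.5-fold change do not apply to lists. Pathway lists past the threshold (8) numbered 0 with camera with estimated correlation, 3 with fry and 5 to 9 with 1 library left out, and 6 to 8 under scalings, filters and limma-voom. Cell type and quality lists (7) numbered 2 with estimated correlation, 7 or 8 under the other alternatives and 7 with each library left out. By exact permutation test 5 of 13 of them were at an unadjusted p under 0.05 with summed CPM and 7 with mean log2 values. Icam1 was past the threshold without ICAM1-low replicate 5 (2.64), with values from 0.29 to 2.64 over single libraries left out, and from 0.54 to 2.22 elsewhere (adjusted p 0.0483 to 0.923 over single libraries left out).

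No block was in the design, since the labels do not say what the replicate numbers share. Checked on the data, not all numbers met the limit of 0.1 set for pairing. Deviations from the group mean correlated at -0.15, 0.12, 0.15 and 0.38 for numbers 1, 2, 3 and 5. Of 8 libraries 5 correlated best with their own number, a hint from the data only. With a replicate block 280 genes were higher and 261 lower. By camera 8 pathway lists were past the threshold (the interferon list came in, the unfolded protein list went out at adjusted p = 0.0615). With an estimated correlation as well there were 0 pathway lists and 2 cell type and quality lists. The log2 fold change of Icam1 with the block was 1.81, not past the threshold. The median of the T and NK cell markers was 6.04 with the block and 2.89 without it. That of the B cell and plasma cell markers was 3.75 with the block and 2.46 without it.

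Medians of lists that were not past the threshold at first changed sign in places, and the cause was not tested. The interferon-stimulated genes (-0.09) had 0.81 with the replicate block (camera adjusted p = 0.0142, and 0.705 with an estimated correlation), 0.0482 with upper-quartile scaling, 0.29 with library sizes only, 0.99 with limma-voom (2.02e-04) and 1.10 without both libraries numbered 5 (1.315e-05) (-0.63 to 1.54 with 1 library left out). The calls with limma-voom and without both libraries numbered 5 used the preset correlation only. Without both libraries numbered 5 the values were 0.11 for NF-kB target and inflammatory genes (-0.76 to 0.20 with 1 left out), 0.32 for tumour-associated neutrophil state genes (-0.57 to 0.38), 0.44 for immunosuppression genes (-0.82 to 0.53), 0.12 for survival and apoptosis genes (-0.58 to 0.28), 1.21 for monocyte markers (-0.60 to 1.54) and -0.24 for mitochondrially encoded genes (-0.22 to 0.37). With the replicate block (either correlation) they were 0.0908 for immunosuppression genes, 0.0124 for survival and apoptosis genes, 1.42 for monocyte markers and 0.0518 for endothelial markers (-1.69 to 0.48). With limma-voom they were 0.32, 0.16 and 1.65 for the immunosuppression, survival and apoptosis, and monocyte lists and -0.0022 for mitochondrially encoded genes, and monocyte markers had 0.29 with the stricter filter, where the erythroid and platelet markers came past the threshold. With 1 library left out, adhesion molecules, integrins and ligands ran from -0.77 to 0.14, oxidative burst genes from -0.28 to 0.38 and erythroid and platelet markers from -0.96 to 0.27. In simulation most changed genes were missed at every fold, 10 of 50 being recovered at 8-fold and 8 of 50 at 16-fold.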

Other observations

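The lists, genes and library groups in this part were chosen after their values were seen. Cartilage matrix genes summed to 1978 to 2479 CPM in ICAM1-low replicates 1 to 3 and to 124 to 378 CPM in ICAM1-high replicates 1 to 3, against 105 and 13.5 CPM in ICAM1-low and ICAM1-high replicate 5. Acan, which encodes the cartilage proteoglycan aggrecan, stood at 197, 234 and 187 CPM in ICAM1-low replicates 1, 2 and 3, and at 0 counts in both libraries numbered 5. Basement membrane and matrix remodelling genes summed to 23370 to 33535 CPM in ICAM1-low replicates 1 to 3, 4913 to 11844 CPM in ICAM1-high replicates 1 to 3, and 4438 and 1507 CPM in ICAM1-low and ICAM1-high replicate 5. In the 20 genes of that list 2 passed the edgeR test, the fibulin genes Fbln2 and Fbln5, with log2 fold changes of -2.44 and -2.90. Neither summed list differed between ICAM1-high and ICAM1-low by the exact permutation test (p = 0.114 for each, n = 4 against 4), although both were lower in ICAM1-high in all 4 pairs. Epcam, Krt8 and Krt18 together stood at 64.2 CPM in ICAM1-low replicate 5 and at a mean of 4.76 CPM in ICAM1-low replicates 1 to 3.

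In ICAM1-low replicate 5, 34 of 35 interferon-stimulated genes and 28 of 30 NF-kB target genes were above the mean of ICAM1-low replicates 1 to 3, by a median of 10.2-fold and 4.95-fold. Neutrophil lists rose as well in this comparison: 14 of 15 neutrophil identity markers and 28 of 30 circulating mature neutrophil genes, by a median of 3.70-fold and 2.11-fold. The macrophage markers had a median difference of 0.09 on the log2 scale in the same comparison. All these values are on the TMM scale, on which this library had a factor of 0.718. ICAM1-high replicate 5 had 5204 summed CPM of interferon-stimulated genes, against 2313 to 3251 CPM in ICAM1-high replicates 1 to 3.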
